A study of Mus musculus with 15 samples.

How the data were processed

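The study compared bulk RNA sequencing of mouse bone marrow-derived dendritic cells (BMDCs) from 2 genotypes, each left unstimulated (US) or given lipopolysaccharide (LPS), a component of Gram-negative bacterial outer membranes that is sensed through TLR4. Per the labels, the mice carried a tamoxifen-inducible Cre recombinase and either a floxed and a wild-type Mysm1 allele (Δ/+ after recombination) or a floxed allele and an allele encoding catalytically inactive MYSM1 (Δ/DN). Marrow was taken more than 12 weeks after tamoxifen, cultured for 9 days, and then held for 18 h with 0 or 10 ng/mL LPS. Ribosomal RNA was depleted and libraries were prepared with the KAPA RNA HyperPrep kit with RiboErase, per the labels' protocols.

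The authors deposited 15 tables, 1 per library, of raw read counts per gene with a gene length, and no normalised values were used. The submitters' processing notes name FastQC, Trimmomatic 0.33, HISAT2 2.2.1, featureCounts, edgeR and bedtools, with the builds mm39 and GRCm39. The role and parameters of each tool were not given in the sources used here, nor was the use of strand in counting. The deposited gene lengths were the same in every table and were not used. Counts of 2 were more frequent than counts of 1 or 3 in most tables, a pattern that counting both mates of a pair would give. This was not tested, and counting limits computed from these counts may be too narrow. Reads were not marked by molecular identifiers, so floors cover counting error only.

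Each table held 50554 genes, of which 48903 (96.7%) matched a symbol in a reference annotation of GRCm38. That annotation was used only for gene names, biotypes and the order of neighbouring genes, and no coordinates are given because its build differs from the one in the notes. Genes without a match took 1.52% of the reads. Genes with near-identical copies, such as histone and ribosomal protein genes, and genes overlapping an antisense gene may have shared reads with those partners, so their values are uncertain.

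Group and replicate were taken from each sample's own title and genotype field. The series description and the sample fields pair the lettered mouse groups with the genotypes in opposite ways, so every direction between genotypes is given as labelled on the samples and would turn round if the series description were right. Total Mysm1 counts could not settle this, because each genotype keeps 1 undeleted allele and the inactive allele differs in the protein it encodes. Library names carry a prefix of 2 or 3, called library set 2 and library set 3 here, whose meaning was not given in the sources used here. Set 2 held 3 Δ/+ US, 3 Δ/+ LPS, 2 Δ/DN US and 2 Δ/DN LPS libraries. Set 3 held 1 Δ/+ US, 2 Δ/DN US and 2 Δ/DN LPS libraries. The names also tie the US and the LPS library of a culture together, giving 8 cultures, 7 of them with both treatments. Cultures were numbered within a genotype by the replicate number in the titles. Whether each culture came from a different mouse was not stated, so the p-values refer to cultures at most and not to mice. The main model took the US and LPS libraries of a culture as independent. Its estimate of spread therefore mixes the spread within and between cultures.

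The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) with robust dispersion, TMM normalisation, the filterByExpr filter with a minimum count of 10, and Benjamini-Hochberg adjustment over the 20865 genes that passed the filter, of which 13797 were protein coding. All 15 libraries entered 1 model with 4 groups and library set as an additive term. A gene was called when its adjusted p was under 0.05, and all adjusted p-values per gene are from this test unless another is named. The 5 comparisons were Δ/DN minus Δ/+ without LPS, Δ/DN minus Δ/+ with LPS, LPS minus US within each genotype, and the difference between those LPS effects. Levels are CPM, the counts of a gene scaled to a common library total after TMM normalisation, given as mean ± SD, and log2 fold changes are given ± their standard error (SE). A fold against a group with no reads was computed against the mean of the libraries' floors, each floor being 3 counts.

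Gene lists were tested with camera and fry on the edgeR counts, dispersions and design of the main model, not on log2 CPM. Camera took a preset inter-gene correlation of 0.01 and, in a second run, an estimated correlation. Benjamini-Hochberg adjustment covered the 26 lists within a comparison. Log2 CPM with a prior count of 2 served for the principal components and the pairing of libraries. Refits of the lists with other libraries or terms used the preset correlation. The 14 gene lists were inflammatory cytokines and chemokines, interferon-stimulated genes, dendritic cell maturation, MHC class II presentation, MHC class I presentation, p53 target genes, cytosolic ribosomal proteins, ribosome biogenesis, cell cycle, glycolysis and HIF-1 targets, cholesterol synthesis and uptake, mitochondrially encoded transcripts, genes linked to MYSM1 in earlier work, and pattern recognition and TLR signalling. The 12 marker lists covered conventional and plasmacytoid dendritic cells, macrophages, monocytes, neutrophils, B cells, T and NK cells, mast cells and basophils, eosinophils, erythroid cells, haematopoietic progenitors, and stromal and endothelial cells. Camera asks whether a list moved relative to the other genes, and fry whether its own genes moved one way on balance. The design, the tests, the lists, the alternatives of the analysis plan and the rule for naming genes were fixed before the data were examined. The rule took the targeted gene, the 8 higher and 8 lower called protein-coding genes with the largest fold change whose mean was at least 5 CPM in the higher group and whose groups did not overlap, and up to 4 members of each list with the smallest p. From those list members the text names a choice made after their values were seen. Where the text names more than 4 members of a list, those past the 4 smallest p fall outside the rule and were chosen after their values were seen, as were Xist, the Y-linked genes, Ddx3x and 7SL RNA.

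The US and LPS libraries of a culture tended to pair. Across genes with an average log2 CPM above 2, the deviations of their log2 CPM from a fit of group and library set were correlated. These correlations ranged from 0.267 to 0.702 over the 7 pairs, with a median of 0.375. Between different cultures of a genotype they ranged from -0.669 to 0.519 (median -0.192). Deviations within a group cancel out, so a positive correlation within pairs lowers that between cultures. The gap between the medians is thus partly built in. Δ/DN US replicate 3 correlated more with LPS replicate 1 (0.519) than with its own pair (0.484), and replicate 2 more with LPS replicate 4 (0.432 against 0.375). The fit with culture as a block was therefore run for the LPS effects and their difference. The regrouping of the 7 paired cultures, used for the overlap of the genotype comparisons, was added after the data were seen. Alternatives were other normalisations (RLE, upper quartile), no low-count filter or a stricter one, DESeq2 1.42.0, limma-voom with and without culture as a random effect, fits without the library set term, in library set 2 alone or with only the groups compared, omission of mitochondrial genes, a fold minimum, a block of replicate number, and omission of each library in turn. Added after the data were seen were fits without culture 3, without culture 4 or without both of the Δ/DN cultures, with a term for the 1 female culture, and without the 7SL RNA genes. Without cultures 3 and 4, Δ/+ US replicate 4 was the only library left in set 3, and the set term absorbed it. That fit therefore compared the same libraries as the fit in set 2 and is no separate check. Without Δ/+ US replicate 4, set 3 held only Δ/DN libraries, and the set term was estimated from those alone. Calls lost in that refit may reflect this or the library's own values, which were not told apart.

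The total of the counts per library ranged from 37256651 to 104041282 reads. On data simulated from these libraries' means and library sizes with 200 genes changed 1.5-fold to 4-fold and a list of 40 more raised by 0.5 log2 units, the fit recovered, of the 200, 20.9% of 1.5-fold, 53.7% of 2-fold and 74.2% of 4-fold changes for the genotype comparison without LPS, with 6 false calls among 20625 unchanged genes. With LPS it recovered 13.4%, 49.3% and 60.6%, with 1 false call. For LPS in Δ/+ the recovery was 22.4%, 46.3% and 71.2%, and for LPS in Δ/DN 19.4%, 44.8% and 71.2%. The false calls there were 2 and 7. For the difference between LPS effects the recovery was 0%, 20.9% and 56.1%, with 4 false calls. Simulated genes varied independently, so the list tests were not checked for correlation between genes. Simulated libraries were drawn independently too, without shared cultures or an outlying library, so false calls may be more frequent in the real data. None of the deposited tables was left out. Results for a few genes are not given here.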

Results

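RNA was sequenced from 15 libraries of mouse bone marrow-derived dendritic cells (BMDCs), antigen-presenting cells grown from marrow in culture, and reads were counted per gene. The cells came from mice in which tamoxifen removed a floxed Mysm1 allele, leaving either a wild-type allele (Δ/+) or an allele for catalytically inactive MYSM1 (Δ/DN). MYSM1 is a deubiquitinase of histone H2A with a known part in blood cell development. There were 4 Δ/+ and 4 Δ/DN libraries without LPS (US), and 3 Δ/+ and 4 Δ/DN libraries with LPS, a bacterial cell wall component that activates dendritic cells. In replicate order the Δ/+ US libraries held 37256651, 68562386, 93291582 and 74831467 reads, and the Δ/+ LPS libraries 94263340, 80341049 and 104041282. The Δ/DN US libraries held 63290541, 66755351, 74268023 and 79018493 reads, and the Δ/DN LPS libraries 77313333, 81447814, 90298588 and 90194773. Between 24749 and 26828 genes had at least 1 read in a library.

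The series description and the sample fields join the lettered mouse groups to the genotypes in opposite ways. Genotypes here are as labelled on the samples, and each direction between genotypes turns round if the series description is right. Total Mysm1 reads cannot tell the alleles apart. Δ/DN culture 4 was the 1 culture with abundant Xist, the RNA that coats the inactive X chromosome of female cells, at 1144 CPM without and 1166 CPM with LPS. The Y-linked genes Kdm5d, Uty, Eif2s3y and Ddx3y had 0 reads in culture 4, which allows up to 0.0288 CPM without and 0.0354 CPM with LPS. In Δ/DN culture 3, Ddx3y, a Y-linked RNA helicase gene, lay at 1.94 CPM without and 3.69 CPM with LPS, against 60.2 ± 11.7 (SD, n = 6) and 85.7 ± 13.6 (SD, n = 5) in the other cultures with Y-linked reads. The US library of that culture held the highest share of 7SL RNA, the RNA of the signal recognition particle, at 10.4% of reads, where the Δ/+ US mean was 5.21 ± 0.36% (SD, n = 4). Its LPS library lay at 4.03%, the highest in Δ/DN LPS but under the Δ/+ LPS mean of 4.52 ± 0.42% (SD, n = 3).

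The comparison of Mysm1 itself asked whether its total RNA differed between the groups. Mysm1 was at 50.4 ± 3.25 CPM (SD, n = 4) in Δ/+ US and 41.2 ± 9.23 CPM (n = 4) in Δ/DN US libraries, and at 43.2 ± 1.71 (n = 3) and 35.3 ± 3.75 CPM (n = 4) with LPS. The log2 difference of Δ/DN from Δ/+ was -0.28 ± 0.14 (SE) without LPS (adjusted p = 0.213) and -0.28 ± 0.16 with LPS (adjusted p = 0.299). LPS moved Mysm1 by -0.23 ± 0.15 in Δ/+ (adjusted p = 0.239) and -0.23 ± 0.14 in Δ/DN (adjusted p = 0.198), and these effects differed by 0.00 ± 0.21 (adjusted p = 0.998). With LPS the log2 difference of Mysm1 between genotypes was called once Δ/DN culture 3 was left out, at -0.29, and the LPS effect in Δ/DN without Δ/DN US replicate 3, at -0.37.

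LPS parted the libraries on the axis of largest variance, which held 56.8% of it. US libraries lay between -94.5 and -52.7 and LPS libraries between 51.3 and 110. The next axis held 11.1%. On it the Δ/+ libraries lay between 11.3 and 60.8 without and 17.7 and 46.4 with LPS, and the Δ/DN libraries between -49.4 and 7.38 and between -53.9 and -4.77.

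**Figure D1:**
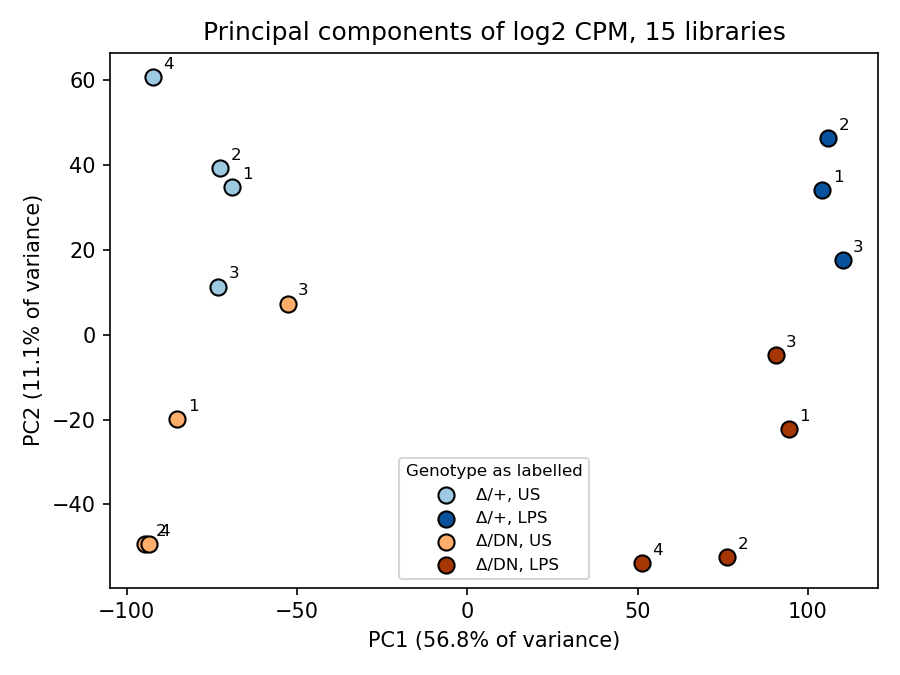
Principal components of log2 CPM, with the axis of largest variance on x and the next on y (both in component units), 1 point per library with its replicate number, coloured by group. US libraries lie between -94.5 and -52.7 on x and LPS libraries between 51.3 and 110.

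Without LPS, the comparison of genotypes asked how resting BMDCs with inactive MYSM1 differed from those with a wild-type allele. In libraries labelled Δ/DN 27 of 40 cell cycle genes rose and 28 of 38 ribosome biogenesis genes fell, but as lists they had adjusted p = 0.303 and adjusted p = 0.202 with an estimated correlation. Without Δ/+ US replicate 4 or Δ/DN US replicate 2, 1 cell cycle gene rose. Sema3c, a secreted axon guidance protein, lay at 5.37 ± 2.04 CPM (SD, n = 4) in Δ/+ and 0.412 ± 0.404 CPM (n = 4) in Δ/DN, a log2 difference of -4.06 ± 0.53 (SE, adjusted p = 0.00228). Epha4, an ephrin receptor, fell from 11.1 ± 5.34 to 1.22 ± 0.493 CPM (-3.14 ± 0.46, adjusted p = 0.00487). Tgfbr3, a TGF-beta co-receptor, fell from 40.7 ± 14.5 to 9.69 ± 2.98 CPM (-2.22 ± 0.24, adjusted p = 0.000783). Arg1, the arginase of alternatively activated macrophages, fell from 120 ± 34.7 to 23.2 ± 13.6 CPM (-2.32 ± 0.52, adjusted p = 0.0206). Mmp19 fell by 2.22, Errfi1 by 2.57, Adgrl2 by 1.92 and Epas1, which encodes HIF-2 alpha, by 1.89 on the log2 scale. Jaml, a junctional adhesion molecule of leukocytes, rose from 21.8 ± 10.4 to 72.3 ± 26.9 CPM (1.99 ± 0.28, adjusted p = 0.0039). Mmp2, a matrix metalloproteinase, rose from 2.31 ± 1.47 to 13.7 ± 9.30 CPM (2.93 ± 0.55, adjusted p = 0.012). St14 rose by 1.81, Tcf19 by 1.68, Adgre4 by 2.22, Grap2 by 1.95, Pacsin1 by 1.84 and the thymidine kinase gene Tk1 by 1.93 log2 units. Of these 16 genes, Epha4, Jaml, Sema3c, St14, Tcf19 and Tgfbr3 kept their call in each of the 8 refits that left out 1 US library, while Arg1, Epas1 and Pacsin1 kept it in 4.

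Of 40 cell cycle genes tested, 27 rose and 0 fell without LPS, and 39 rose when adjusted over the list alone, with a median log2 difference of 1.07. Gins2 (1.19 ± 0.20), Cdc6 (1.67 ± 0.31) and Rrm2 (1.37 ± 0.26), all used in DNA replication, rose, as did the spindle gene Tpx2 (1.08 ± 0.21). Camera placed the cell cycle list above the other genes (adjusted p = 1.5e-25), with adjusted p = 0.303 with an estimated correlation. The list rose in 36 genes without Δ/DN culture 3, in 35 without culture 4 and in 16 without both. Left out singly, Δ/+ US replicate 4 (the only Δ/+ library of set 3) brought its count of genes that rose to 1, replicate 2 to 6 and replicate 1 to 13, and Δ/DN US replicate 2 brought it to 1 and replicate 4 to 9, while the median stayed between 0.85 and 1.06. Of 38 ribosome biogenesis genes, 28 fell and 0 rose, and 30 fell when adjusted over the list alone, with a median of -0.54. Gnl3 (nucleostemin) fell from 55.4 ± 9.27 to 33.2 ± 3.15 CPM (-0.79 ± 0.09, adjusted p = 0.000783), and Tsr1 (-0.75 ± 0.09), Nolc1 (-0.78 ± 0.10) and Noc3l (-0.68 ± 0.09) fell with it. These 4 genes kept their call in each refit without 1 US library. Camera gave adjusted p = 4.1e-26 for the ribosome biogenesis list, and adjusted p = 0.202 with an estimated correlation. The list fell in 29 genes without Δ/DN culture 3, 26 without culture 4 and 22 without both, and in 11 without Δ/+ US replicate 4 and 16 without Δ/DN US replicate 2. Of 81 cytosolic ribosomal protein genes, 16 fell and 0 rose, and 20 fell when adjusted over the list alone (median -0.20), among them Rpl29 (-0.36 ± 0.08) and Rpl24 (-0.44 ± 0.10). Their camera adjusted p was 3.6e-08, and the adjusted p = 0.637 with an estimated correlation. Ribosomal protein genes fell in 42 cases without culture 3, 15 without culture 4 and 18 without both. Leaving out Δ/+ US replicate 1, 2, 3 or 4 gave 10, 7, 11 or 0 that fell, and leaving out Δ/DN US replicate 1, 2, 3 or 4 gave 8, 2, 41 or 4.

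Among 32 p53 target genes, Psrc1 (1.43 ± 0.31), Phlda3 (0.50 ± 0.12) and Sesn2 (0.57 ± 0.15) rose without LPS and Aen (-0.59 ± 0.09) fell, while 12 rose and 1 fell when adjusted over the list alone. The p53 list had a median of 0.31 and camera adjusted p = 0.00879, with adjusted p = 0.462 with an estimated correlation. Sesn2 kept its call in 3 of 8 refits without 1 US library and Phlda3 in 4. Psrc1 is also a mitotic spindle gene. The count of p53 targets that rose was 9 without culture 3, 3 without culture 4 and 2 without both. It was 0 without Δ/+ US replicate 2 or 4 or Δ/DN US replicate 2, 2 without Δ/+ US replicate 1 or Δ/DN US replicate 1 or 4, and 9 without Δ/DN US replicate 3. Of 35 pattern recognition and TLR signalling genes, Tlr9 (1.10 ± 0.19), Tlr1 (1.52 ± 0.32) and Tlr6 rose, and Cd14 (-1.61 ± 0.27), Tlr4 (-0.66 ± 0.12), Tlr2, Tirap, Nlrp3 and Clec4e fell, with 3 up and 9 down when adjusted over the list alone. Where more than 4 members of a list are named, here and in the other comparisons, those past the 4 smallest p were chosen after their values were seen. Camera gave adjusted p = 0.019 for this list, and adjusted p = 0.637 with an estimated correlation. Cd14 and Tlr4 form part of the receptor for LPS. Cd14 lay at 161 CPM in Δ/DN US replicate 3 and at 84.0 ± 51.7 CPM over the 4 Δ/DN US libraries. Of 26 glycolysis and HIF-1 target genes, Egln3 (-1.53 ± 0.22), Vegfa (-1.85 ± 0.32), Ero1a (-0.73 ± 0.15), P4ha2 and Hk2 fell, Tpi1 (0.46 ± 0.09) and Hk1 rose, and 2 rose and 6 fell when adjusted over the list alone. Camera gave adjusted p = 0.00879 for them, and adjusted p = 0.637 with an estimated correlation. Of 21 cholesterol genes 2 fell, among them Insig1 (-0.83 ± 0.25), and 1 when adjusted over the list alone, with camera adjusted p = 0.00185 and adjusted p = 0.652 with an estimated correlation. Insig1 kept its call in 1 of 8 refits without 1 US library.

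Among 32 inflammatory cytokine and chemokine genes, Il12b (1.61 ± 0.29) and Ccl17 (0.72 ± 0.21) rose without LPS and Vegfa and Cxcl1 (-1.95 ± 0.54) fell, the same number each way when adjusted over the list alone (camera adjusted p = 0.141). Without Δ/DN culture 3 camera called the cytokine list lower at the preset correlation (adjusted p = 5.8e-10). The full fit estimated a correlation of 0.467 for this list, so that p-value may be far too small. Ccl17 kept its call in 1 of 8 refits without 1 US library, Cxcl1 in 2 and Il12b in 7, and of the genes below H2-DMb2 kept it in 3 and Slamf1 and Serpinb6b in 4. Il12b, a subunit of IL-12 and IL-23, lay at 2.13 ± 1.09 CPM in Δ/+ and 5.25 ± 2.51 CPM in Δ/DN. Of 30 dendritic cell maturation genes, Slamf1 (1.94 ± 0.46) and Serpinb6b (1.34 ± 0.36) rose, also when adjusted over the list alone, with camera adjusted p = 0.0186 and adjusted p = 0.652 with an estimated correlation. That call was lost without Δ/DN culture 3 (adjusted p = 0.326) and without the library set term (adjusted p = 0.304). Of 14 MHC class II genes, Ciita (1.36 ± 0.29), the master transactivator of that pathway, and H2-DMb2 (0.58 ± 0.15) rose, and camera gave adjusted p = 0.0814. Of 19 MHC class I genes 0 passed the edgeR test (median 0.39), with camera adjusted p = 0.019 and adjusted p = 0.652 with an estimated correlation. The MHC class I call was lost without Δ/DN culture 3 (adjusted p = 0.546), and Δ/DN US replicate 3 stood apart in Tap2 (142 CPM) and Psme2 (126 CPM). In library set 2 and without both cultures 3 and 4 the maturation and MHC class I lists leaned the other way without a call (adjusted p from 0.740 to 0.764). These 2 fits compare the same libraries and are not separate checks. Of 49 interferon-stimulated genes 0 passed, with a median of 0.38 and camera adjusted p = 0.166. Their mean centred log2 CPM was -0.02 in Δ/DN US replicate 3 against -2.34 to -1.90 in the other 3, and -3.21 in Δ/+ US replicate 4 against -1.75 to -1.08 in the other 3, and within library set 2 alone 24 of the 49 genes fell, with a median of -0.79. With both Δ/DN cultures 3 and 4 left out 29 of the 49 fell. None of 13 mitochondrially encoded transcripts passed (median -0.04). Of 10 genes linked to MYSM1 in earlier work, Runx1 (-0.39 ± 0.08) fell, with 1 up and 1 down when adjusted over the list alone, and Gata2, a stem cell and mast cell factor, was at 1.83 ± 0.60 (adjusted p = 0.0704).

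Markers of other cell types were measured in the same libraries. Of 14 conventional dendritic cell markers, Kmo (2.06 ± 0.40), Dpp4 (1.24 ± 0.36) and Xcr1 (2.64 ± 0.61, 0.0314 to 0.167 CPM) rose in Δ/DN US libraries, with camera adjusted p = 0.00879 and adjusted p = 0.303 with an estimated correlation. Of 17 macrophage markers, the complement genes C1qa (0.94 ± 0.14), C1qb and C1qc (0.67 ± 0.17) and Gpnmb (1.11 ± 0.20) rose while Arg1 and Cd68 (-0.37 ± 0.10) fell. The plasmacytoid marker Pacsin1 (1 of 10), the neutrophil marker Csf3r (1 of 18) and the mast cell and basophil marker Cd200r3 (1 of 9) rose, and neutrophil and mast cell lists (medians 1.05 and 1.31) had camera adjusted p = 0.00879, with adjusted p = 0.652 and adjusted p = 0.637 with an estimated correlation. Hbb-bt (2.36 ± 0.54) and Hbb-bs (1.93 ± 0.56) rose among 5 erythroid markers, at 0.735 and 0.428 CPM in Δ/DN, with a list median of 1.78 and camera adjusted p = 0.0141 and adjusted p = 0.303 with an estimated correlation. Cd34 (3.30 ± 0.63) and Myb (2.04 ± 0.50) rose among 8 haematopoietic progenitor markers, Cd34 from 0.785 ± 0.54 to 6.41 ± 6.50 CPM. Sparc and Col1a2 rose and Lepr (-1.08 ± 0.21) and Pecam1 (-1.11 ± 0.25) fell among 12 stromal and endothelial markers, whose median (-0.12) and mean (0.35) differ in sign. The B cell gene Blk (-2.07 ± 0.54, 1 of 8) and the T and NK cell gene Il7r (-0.89 ± 0.23, 1 of 9) fell, and 0 of 8 monocyte and 0 of 9 eosinophil markers passed. When adjusted over the list alone, 3 plasmacytoid, 3 mast cell and 3 progenitor markers rose, and 2 T and NK cell markers and 1 monocyte marker fell. Dpp4 and Cd200r3 kept their call in 1 of 8 refits without 1 US library, Col1a2 in 2, Myb, Hbb-bs and Blk in 3, C1qc, Sparc, Arg1, Il7r and Pacsin1 in 4, and Xcr1, Hbb-bt and Pecam1 in 5. Without the library set term 1 conventional dendritic cell marker rose instead of 3 (camera adjusted p = 0.0764) and 1 macrophage marker instead of 4. By fry, which asks whether the genes of a list move on balance 1 way and does not compare them with other genes, 6 of the 26 lists passed without LPS. These were ribosome biogenesis (adjusted p = 0.000703), conventional (0.0093) and plasmacytoid (0.0473) dendritic cell markers, and cell cycle genes, p53 targets and erythroid markers (0.019 each), while ribosomal proteins had 0.086.

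Without LPS 1046 genes rose and 1138 fell in Δ/DN as labelled, 2184 in all, of 20865 tested. Of these, 657 changed by at least 1 log2 unit, 502 up and 155 down. The libraries of the genotypes did not overlap for 12.5% of genes, where chance gives 2.86%. The total was 174 (54 up, 120 down) without Δ/+ US replicate 4, 350 (98 up, 252 down) without Δ/DN US replicate 2, 549 (171 up, 378 down) without Δ/+ US replicate 2, 882 without Δ/DN US replicate 4, 1418 without Δ/+ US replicate 1 and 3403 without Δ/DN US replicate 3. Δ/+ US replicate 4 was the only Δ/+ library of set 3, so without it the set term rested on Δ/DN libraries alone. How much of the fall to 174 came from that was not tested. Within library set 2 the total was 1271 (410 up, 861 down), of which 867 were among the 2184, each in the same direction.

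**Figure D2:**
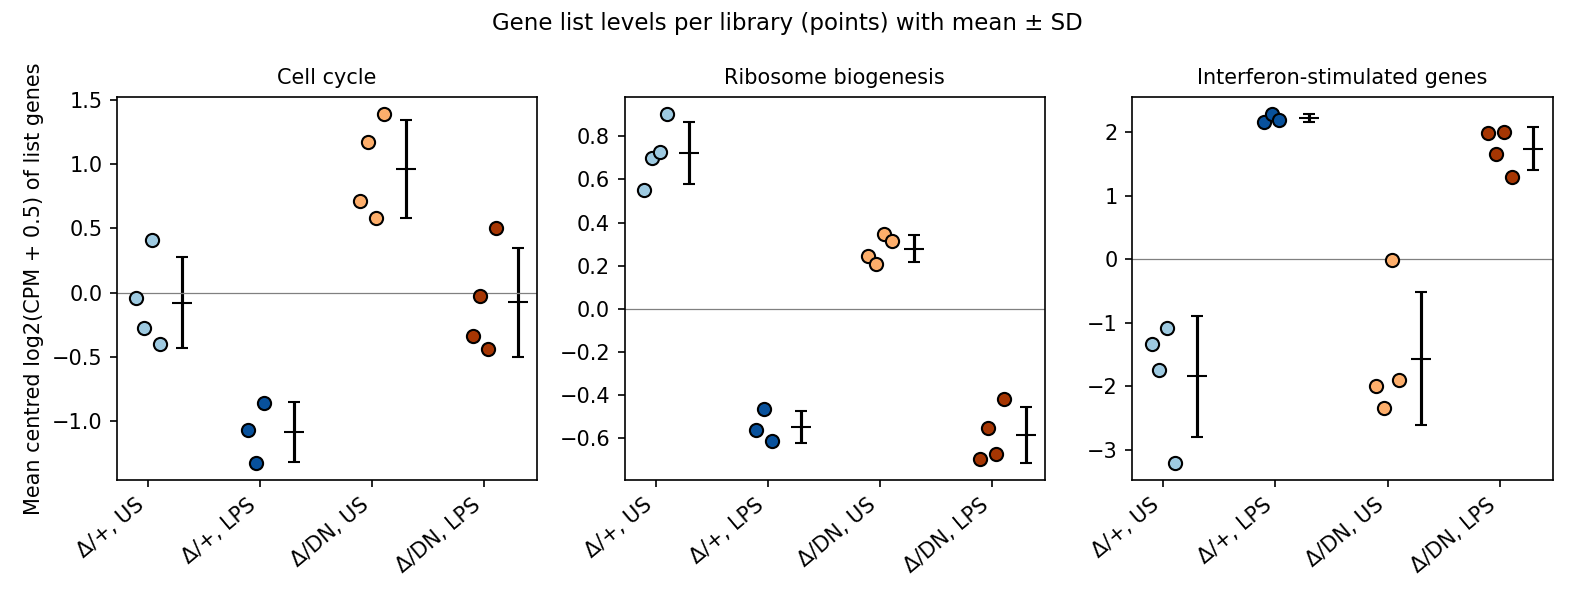
Mean centred log2 CPM per library (y, log2 units) of the cell cycle, ribosome biogenesis and interferon-stimulated gene lists, by group on x, with points for libraries and bars for mean ± SD. Cell cycle genes are higher in Δ/DN as labelled, by a median of 1.07 without LPS, and Δ/DN US replicate 3 stands apart from the other 3 in the interferon-stimulated list.

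With LPS, the comparison asked how activated BMDCs of the genotypes differed. Il10, an anti-inflammatory cytokine, lay at 31.5 ± 18.6 CPM (SD, n = 3) in Δ/+ and 4.54 ± 3.19 CPM (n = 4) in Δ/DN, a log2 difference of -3.08 ± 0.81 (SE, adjusted p = 0.0391). Il33, an alarmin cytokine, fell from 72.9 ± 20.4 to 8.97 ± 7.06 CPM (-2.78 ± 0.67, adjusted p = 0.0317), and Penk, which encodes the opioid precursor proenkephalin, from 34.7 ± 1.38 to 4.33 ± 2.09 CPM (-2.98 ± 0.44, adjusted p = 0.00513). Epha4 fell from 122 ± 40.5 to 14.4 ± 4.03 CPM (-3.04 ± 0.48, adjusted p = 0.00774). The scavenger receptor gene Marco (-2.83 ± 0.52), Tmem267 (-3.17 ± 0.70), Gfpt2 (-2.77 ± 0.58) and Car4 (-2.54 ± 0.62) also fell. Nedd4, a ubiquitin ligase, rose from 17.9 ± 5.0 to 67.0 ± 42.4 CPM (2.39 ± 0.45, adjusted p = 0.0141), and Etl4 from 1.72 ± 0.857 to 7.01 ± 1.88 CPM (2.2 ± 0.31, adjusted p = 0.0039). Asb2 rose by 2.59, Siglece by 2.32, Pacsin1 by 2.22, Limd2 by 2.08 and the linker histone gene H1f10 by 2.00 log2 units. Among these genes Epha4, Etl4 and Penk kept their call in each of the 7 refits that left out 1 LPS library. Il10, Car4 and Siglece kept it in 3 of the 7, Il33, Gfpt2, Limd2 and Pacsin1 in 4 and Asb2 in 2.

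Of 40 cell cycle genes 19 rose and Pcna (-0.65 ± 0.15) fell with LPS, and 35 rose and 1 fell when adjusted over the list alone, with a median of 1.20. Mcm2 (1.67 ± 0.36), Uhrf1 (1.59 ± 0.36) and Rrm2 (1.40 ± 0.31) rose. The cell cycle list had camera adjusted p = 3.0e-18, and adjusted p = 0.660 with an estimated correlation. It rose in 28 genes without Δ/DN culture 3, 30 without culture 4 and 22 without both, in 0 without Δ/+ LPS replicate 1 or 2 or Δ/DN LPS replicate 2, and in 12 without Δ/+ LPS replicate 3. Of 81 ribosomal protein genes 18 fell, 41 when adjusted over the list alone, among them Rpl23 (-0.51 ± 0.11), Rps27 (-0.60 ± 0.13) and Rpl24 (-0.50 ± 0.11), with a median of -0.28. Their camera adjusted p was 1.3e-12, and the adjusted p = 0.660 with an estimated correlation. They fell in 32 cases without culture 3, 25 without culture 4 and 27 without both, in 0 without Δ/+ LPS replicate 1 or 2 or Δ/DN LPS replicate 2, and in 8 without Δ/+ LPS replicate 3 or Δ/DN LPS replicate 4. Of 32 p53 targets 10 rose, among them Pmaip1 (1.16 ± 0.21), Phlda3 (0.76 ± 0.15), Sesn2 (0.79 ± 0.17) and Ccng1 (0.46 ± 0.10), Mdm2 fell, and 13 rose and 2 fell when adjusted over the list alone. Pmaip1 encodes the pro-apoptotic protein NOXA. Camera gave adjusted p = 0.00073 for p53 targets, and adjusted p = 0.660 with an estimated correlation. 11 of them rose without culture 3, without culture 4 or without both, 4 without Δ/+ LPS replicate 1, 0 without replicate 2, 6 without replicate 3 and 1 without Δ/DN LPS replicate 2. Of 38 ribosome biogenesis genes Noc3l (-0.47 ± 0.10), Nolc1 (-0.47 ± 0.11), Nop56 and Ddx21 fell and Nop16 (0.59 ± 0.16) rose, 7 and 1 when adjusted over the list alone, with camera adjusted p = 0.0205 and adjusted p = 0.887 with an estimated correlation, and adjusted p = 0.186 without Δ/DN culture 3. They fell in 1 case without Δ/+ LPS replicate 1 and in 0 without Δ/+ LPS replicate 2 or Δ/DN LPS replicate 2, and Nop16 kept its call in 2 of 7 refits and Nop56 in 3.

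Of 26 glycolysis and HIF-1 target genes Egln3 (-2.47 ± 0.24, adjusted p = 0.000781), Ero1a (-0.97 ± 0.17), Bnip3 and P4ha2 fell and Tpi1 (0.57 ± 0.10) and Hk1 rose with LPS, and 7 fell and 2 rose when adjusted over the list alone. Camera gave adjusted p = 0.0205 for them, and adjusted p = 0.660 with an estimated correlation, and the call was lost without Δ/DN culture 3 (adjusted p = 0.157). Interferon-stimulated genes had a median of -0.43 with 0 of 49 past the edgeR test, camera adjusted p = 0.0205 and adjusted p = 0.920 with an estimated correlation, and adjusted p = 0.0583 without Δ/DN culture 4. Il10 and the IL-1 receptor antagonist gene Il1rn (-0.90 ± 0.26) fell among 32 cytokine genes (camera adjusted p = 0.0761), 3 when adjusted over the list alone, while Il23a was at -1.38 ± 0.40 (adjusted p = 0.0512) and Il12b at 0.97 ± 0.31 (adjusted p = 0.0679). Tlr9 (1.38 ± 0.21) and Ticam2 rose and Tirap, Tnfaip3 and Nlrp3 fell among 35 TLR signalling genes, with 5 up and 7 down when adjusted over the list alone. Ciita (1.65 ± 0.33) and H2-Eb2 (1.84 ± 0.37) rose among 14 MHC class II genes, and the PD-1 ligand gene Pdcd1lg2 (0.82 ± 0.20) among 30 maturation genes. None of 19 MHC class I, 21 cholesterol or 13 mitochondrial genes passed. Gata2 (2.81 ± 0.71) and Trp53 (0.34 ± 0.09) rose among 10 genes linked to MYSM1. Of these genes Il1rn kept its call in 1 of 7 refits without 1 LPS library, Gata2, Trp53 and Tnfaip3 in 2, Tirap in 3, and Ciita, H2-Eb2, Pdcd1lg2 and Bnip3 in 4.

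Among cell type markers with LPS, the mast cell and basophil genes Gata2 and Cd200r3 (1.10 ± 0.26) rose in 2 of 9 tested, with camera adjusted p = 0.0173 and adjusted p = 0.660 with an estimated correlation. Csf3r (1.02 ± 0.27) rose among 18 neutrophil markers, 4 when adjusted over the list alone, with camera adjusted p = 0.0205 and adjusted p = 0.887 with an estimated correlation. Gpnmb (1.57 ± 0.23) and C1qa (0.75 ± 0.16) rose and Cd68 (-0.47 ± 0.12) and Arg1 (-2.12 ± 0.57) fell among 17 macrophage markers, whose median (0.11) and mean (-0.07) differ in sign. Dpp4 (1.44 ± 0.41) rose and Clec10a (-1.04 ± 0.21) fell among 14 conventional dendritic cell markers. Cd34 (2.45 ± 0.70) rose and Meis1 (-1.05 ± 0.28) fell among 8 progenitor markers. The monocyte gene Cx3cr1 (3.32 ± 0.82) and the plasmacytoid gene Pacsin1 rose, and the eosinophil gene Ear1 (-1.87 ± 0.51) and the stromal gene Lepr (-1.84 ± 0.24) fell. None of 8 B cell, 9 T and NK cell or 5 erythroid markers passed. Arg1 and Dpp4 kept their call in 1 of 7 refits without 1 LPS library, and Cd34, Csf3r, Ear1, Gata2 and Meis1 in 2, and Cd200r3, Cd68, Cx3cr1 and Pacsin1 in 4. By fry 1 of the 26 lists passed with LPS, p53 targets (adjusted p = 0.0174), and cell cycle genes and ribosomal proteins had 0.0783 each.

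With LPS 1121 genes rose and 674 fell in Δ/DN as labelled, 1795 in all. Of these, 659 changed by at least 1 log2 unit, 449 up and 210 down. The genotypes did not overlap for 24.6% of genes, where chance gives 5.71%. The total was 90 without Δ/+ LPS replicate 2, 184 without Δ/DN LPS replicate 2, 312 without Δ/+ LPS replicate 1 and 1178 without Δ/DN LPS replicate 4, and 12 in a fit of only these 7 libraries. All 3 Δ/+ LPS libraries were in library set 2, so in the fit of 7 libraries the set term rested on Δ/DN libraries alone. Within library set 2, with the US libraries in the model, 1933 genes were called.

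**Figure D3:**
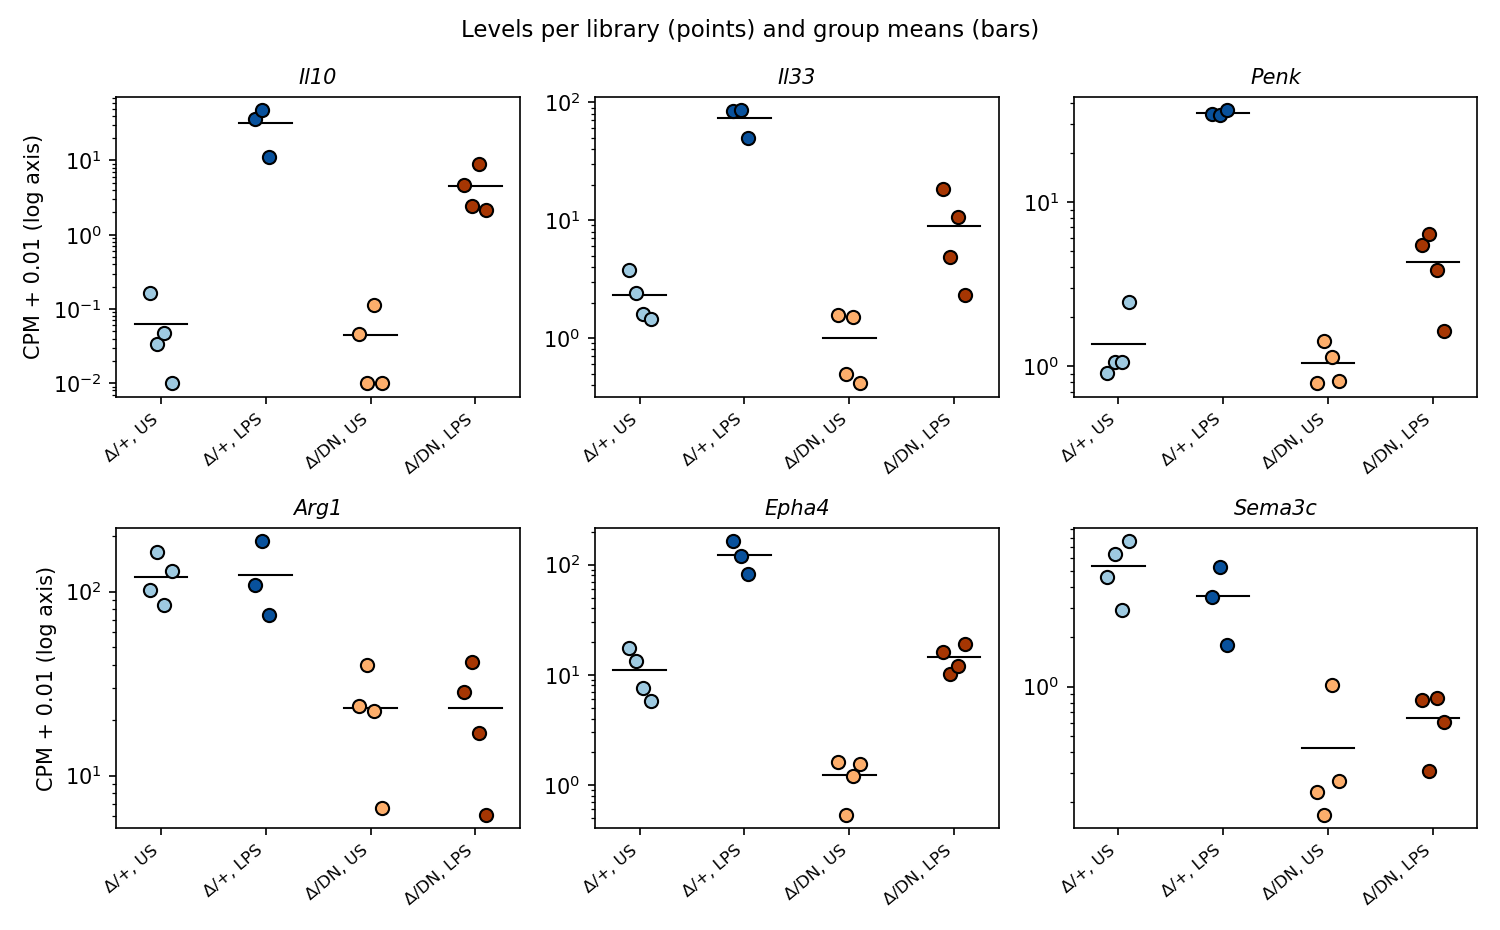
Expression (CPM + 0.01, log axis) of Il10, Il33, Penk, Arg1, Epha4 and Sema3c in each library by group, with horizontal bars at the group means. With LPS the mean of Il10 is 31.5 CPM in Δ/+ and 4.54 CPM in Δ/DN.

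Whether the genotype differences without and with LPS fell on the same genes was tested by their overlap. Of the genes that were higher in Δ/DN as labelled, 408 were higher under both treatments, where independent lists would share 56.2. Of those that were lower, 280 were lower under both, against 36.8 for independent lists, and 5 genes changed in opposite directions. The 688 in all became 401 without the library set term and 1317 without Δ/DN culture 3. Epha4 and Egln3 were among those lower, and Gpnmb among those higher, under both treatments, and these 3 kept both calls in each refit without 1 library. Across genes, which are not independent replicates, the differences correlated at r = 0.501 with a covariance of 0.254. The US and LPS libraries came from the same cultures, so the cultures were regrouped in all 35 ways with each pair kept together. The 34 other groupings gave correlations from 0.101 to 0.635 (median 0.261), and 5 of 35 reached the real value, so the correlation did not stand out from that of shared cultures. They shared 0 to 9 calls, but most of them called few genes or 0, and part of the overlap may come from shared cultures.

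In Δ/+ cells, the LPS comparison asked which genes responded to the stimulus. LPS raised several inflammatory genes from low levels: Il12b went from 2.13 ± 1.09 CPM (SD, n = 4) to 2973 ± 1175 CPM (n = 3), a log2 change of 10.31 ± 0.40 (SE, adjusted p = 8.6e-10). Il6 went from 3.51 ± 1.20 to 2678 ± 434.5 CPM (9.57 ± 0.61), and the inducible nitric oxide synthase gene Nos2 from 2.35 ± 0.531 to 2361 CPM (10.18 ± 0.94). Ptgs2, the inducible cyclooxygenase, went from 4.78 ± 2.53 to 4380 CPM (9.89 ± 0.72). Il23a (10.30 ± 0.54), Il12a (9.65 ± 0.65) and Il10 (9.65 ± 0.97) rose, and Shisa3 went from 0 reads in all 4 US libraries to 8.14 ± 0.92 CPM, at least 199-fold higher against the mean of the libraries' floors. Cd300lb, an activating receptor gene, fell from 33.3 ± 7.92 to 0.764 ± 0.156 CPM (-5.45 ± 0.40, adjusted p = 1.9e-07). B3gnt7 (-5.12 ± 0.22), the cannabinoid receptor gene Cnr2 (-5.01 ± 0.36), C5ar2 (-4.90), Neurl1b (-4.80), Sbk1 (-4.49), Galnt9 (-4.18) and Ppargc1b (-4.16) fell. In Δ/DN cells Il6 went from 1.71 ± 1.20 to 1693 ± 551.7 CPM (n = 4 each, 9.95 ± 0.61, adjusted p = 8.4e-08). Il12b (9.67 ± 0.38), Ptgs2 (9.46 ± 0.70), Il12a (9.11 ± 0.58), Il23a (9.02 ± 0.52), Nos2 (8.60 ± 0.89), Cxcl1 (7.83 ± 0.64) and Tnfsf15 (7.63) rose. Sbk1 (-4.19 ± 0.28), Neurl1b (-4.17 ± 0.24), Lpar5 (-4.16 ± 0.40), Cd300lb (-4.01 ± 0.31), Ppargc1b (-4.0), B3gnt7 (-3.98 ± 0.18), Ankrd63 (-3.77) and Gpr146 (-3.73) fell in Δ/DN.

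Of 32 cytokine and chemokine genes 31 rose in each genotype, with medians of 6.09 in Δ/+ and 6.39 in Δ/DN. In Δ/+ 31 rose and 1 fell, and in Δ/DN 31 rose and 0 fell, when adjusted over the list alone. Camera gave adjusted p = 1.0e-34 in Δ/+, with adjusted p = 0.134 with an estimated correlation, and 4.6e-39 in Δ/DN, with adjusted p = 0.0396 with an estimated correlation. All 49 interferon-stimulated genes rose in Δ/+ and 48 in Δ/DN, also when adjusted over the list alone, with medians of 3.71 and 2.85. Gbp5 rose by 5.17 and 4.26, and the antiviral gene Mx1 by 4.06 and 3.31. Camera adjusted p was 5.5e-17 and 2.0e-13 for this list, with adjusted p = 0.440 and adjusted p = 0.622 with an estimated correlation. Without Δ/DN culture 3 all 49 rose in Δ/DN, with a median of 3.37. Of 30 maturation genes 24 rose in each genotype, 24 and 26 when adjusted over the list alone, with Cd80 up by 2.23 and 2.29, Nfkb2 up by 2.12 in both, and Tnfrsf4 down in Δ/+. Camera adjusted p was 2.4e-17 and 2.4e-19 for them, with adjusted p = 0.134 and adjusted p = 0.168 with an estimated correlation. Of 19 MHC class I genes 16 rose in Δ/+ and 18 in Δ/DN, 16 and 19 when adjusted over the list alone, with Tap2 up by 1.88 and 1.40 and Psme2 by 2.10 and 1.46. Camera adjusted p was 9.0e-08 and 8.1e-06 there, with adjusted p = 0.440 and adjusted p = 0.622 with an estimated correlation. H2-Ab1 (0.76, 0.81), Cd74 (0.75, 0.74), H2-Eb1 and H2-Aa rose in both genotypes among 14 MHC class II genes, with H2-DMb1 in Δ/+ and H2-Eb2 in Δ/DN as the others that rose and H2-DMa down in Δ/DN. Of 35 TLR signalling genes 24 rose in each genotype, 25 and 24 when adjusted over the list alone, with Nfkbiz up by 4.68 and 5.13. Tlr4 (-1.49, -0.82), Irak1, Irak4 and Irf3 fell in both, and Clec7a in Δ/+. Camera adjusted p for TLR genes was 4.5e-11 in Δ/+, with adjusted p = 0.134 with an estimated correlation, and 4.7e-15 in Δ/DN, with adjusted p = 0.0424 with an estimated correlation.

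Of 38 ribosome biogenesis genes 34 fell in Δ/+ and 32 in Δ/DN, 34 in each when adjusted over the list alone, with medians of -1.14 and -0.64, and Rrs1 and Ltv1 rose in Δ/DN. Gnl3 moved by -1.95 and -1.49, Tsr1 by -1.86 and -1.42 and Rrp12 by -2.25 and -1.38. Camera adjusted p was 9.8e-22 and 1.1e-14 for them, with adjusted p = 0.134 and adjusted p = 0.198 with an estimated correlation. Of 40 cell cycle genes 27 fell in Δ/+ and 31 in Δ/DN, 31 in each when adjusted over the list alone, with a median of -1.16 in both. Cdc20 moved by -2.96 and -2.25 and Mcm2 by -2.05 and -1.46, while Tyms rose in both and Gins2, Tpx2 and Pcna rose in Δ/+. Camera adjusted p was 0.000823 and 3.9e-05 for the cell cycle list, with adjusted p = 0.849 and adjusted p = 0.697 with an estimated correlation. Of 21 cholesterol genes 16 fell in Δ/+ and 12 in Δ/DN, 17 and 13 when adjusted over the list alone, with Dhcr7 at -2.46 and -2.07 and Stard4 at -2.11 and -1.49, and Idi1 rose in both. Camera adjusted p was 1.1e-05 and 0.00258 there, with adjusted p = 0.564 and adjusted p = 0.697 with an estimated correlation, and the Δ/DN call was lost without culture 3 (adjusted p = 0.064). Of 81 ribosomal protein genes 18 rose in Δ/+ and 13 in Δ/DN, but 13 and 6 when adjusted over the list alone, with Rpl24 up by 0.71 and 0.65, and camera gave adjusted p = 0.0404 in Δ/+, with adjusted p = 0.849 with an estimated correlation, and 0.165 in Δ/DN. Ribosomal protein genes rose in 41 cases in Δ/+ and 11 in Δ/DN without cultures 3 and 4, in 33 and 10 without culture 4 and in 26 and 28 without culture 3. Of 32 p53 targets 11 rose and 14 fell in each genotype, 11 and 15 in Δ/+ and 12 and 14 in Δ/DN when adjusted over the list alone, with Plk2 up by 2.95 and 2.70 and Phlda3 at -1.75 and -1.49. Of 26 glycolysis and HIF-1 genes 9 rose in Δ/+ and 8 in Δ/DN, and as many rose when adjusted over the list alone, with Egln3 up by 2.35 and 1.42 and Ndrg1 by 1.82 and 1.72, and Pdk1 fell in both with Slc16a3 in Δ/+ and Car9 in Δ/DN. The mitochondrial transcripts ATP8, COX2 and ATP6 rose in Δ/+, and 10 of 13 rose in Δ/DN (1 and 12 when adjusted over the list alone), where the counts were 7 and 7 without Δ/DN culture 3, 4 and 6 without culture 4, and 5 and 1 without both, in the order Δ/+ and Δ/DN. In Δ/+ COX2 and ATP6 kept their call in 3 of 7 refits without 1 library. Gfi1, Cdkn1a and Id2 rose and Runx1 (-1.30, -1.19) and Trp53 (-0.72, -0.45) fell in both genotypes among 10 genes linked to MYSM1.

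Of 14 conventional dendritic cell markers 6 rose in Δ/+ and 7 in Δ/DN with LPS, with Irf8 up by 1.78 and 2.09 and Ccr7, the lymph node homing receptor gene, by 1.43 and 1.46. Batf3 fell in both genotypes, and Cd209a, Clec10a and Kmo in Δ/DN. The macrophage genes Csf1r (-1.08, -0.81) and Trem2 fell and Mertk, Adgre1 and Ms4a7 rose in both, with Cd68 up in Δ/+. Vcan (3.13, 3.68), Plac8 and Ly6c2 rose and Ccr2 (-2.15, -1.79) fell among 8 monocyte markers. Csf3r (1.70, 1.5) and Lcn2 rose and Cxcr2 fell among 18 neutrophil markers. Tcf4 (2.99, 2.68) and Ccr9 rose and Lair1 and Spib fell among 10 plasmacytoid markers. Cd247 (4.26, 3.69), Lck and Gzmb rose in both among 9 T and NK cell markers, with Il7r up and Klrb1c down in Δ/DN. The mast cell and basophil gene Hdc rose by 7.06 and 5.68, with Cd200r3 down in Δ/+, and the eosinophil gene Il5ra rose and the B cell gene Cd22 fell in both. Hbb-bt and Hbb-bs rose in Δ/+ and 0 of 5 erythroid markers passed in Δ/DN. Sox4 and Meis1 fell in both among 8 progenitor markers, with Myb up in Δ/+ and Gfi1b down in Δ/DN. Pdgfrb, Pdgfra and Lum rose in both among 12 stromal markers, with Dcn up and Pecam1 down in Δ/+ and Lepr down in Δ/DN. Lum had 0 reads in all US libraries. With LPS it lay low, at 0.240 ± 0.083 CPM (SD, n = 3) in Δ/+ and 0.0876 ± 0.0961 CPM (n = 4) in Δ/DN. Against the mean floors these were at least 5.86-fold and 2.54-fold higher. In Δ/+ Cd200r3 and Myb kept their call in 3 of 7 refits without 1 library, and in Δ/DN Il5ra kept it in 2 of 8, Gfi1b in 3 and Cd22 in 6.

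LPS called 9951 genes in Δ/+ (4664 rose, 5287 fell) and 10052 in Δ/DN (4824 rose, 5228 fell). The libraries did not overlap for 52.1% of genes in Δ/+, where chance gives 5.71%, and for 40.9% in Δ/DN, where chance gives 2.86%. Both genotypes called 8227 genes, 8220 of them in the same direction, while 1724 passed in Δ/+ alone and 1825 in Δ/DN alone. By fry 16 of the 26 lists passed for LPS in Δ/+ and 17 in Δ/DN. All 16 genes named by size of change in each genotype kept their call in each refit that left out 1 library, which some list members named above did not.

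Whether genotype altered the LPS response was tested by the difference between those effects. Emilin1, an extracellular matrix glycoprotein gene, passed: it went from 16.1 ± 2.62 to 28.7 ± 4.95 CPM with LPS in Δ/+ and from 24.7 ± 3.13 to 13.3 ± 2.10 CPM in Δ/DN, a difference of -1.72 ± 0.22 log2 units (adjusted p = 0.0327). It was the 1 gene called by edgeR, and 0 rose. At an unadjusted p under 0.05 1873 genes passed, while DESeq2 called 118 and limma-voom 0. Emilin1 kept its call in 5 of 15 refits without 1 library, in which the number of calls ranged from 0 to 15, the latter without Δ/DN LPS replicate 3. With culture as a block 156 genes were called, 112 with a positive difference (Δ/DN as labelled less Δ/+) and 44 with a negative one, among them Penk (-3.16 ± 0.33), Emilin1 (-1.70 ± 0.20), Il33 (-1.79 ± 0.24), Etl4 (1.74 ± 0.25) and B3gnt7 (1.21 ± 0.16). A positive difference can be a smaller fall, as for B3gnt7, which LPS lowered in both genotypes. Another grouping of the cultures called 304 genes in that fit, so chance is not excluded for the 156.

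None of the 26 lists had a member past the edgeR test of the difference over all genes. Ribosome biogenesis genes had a median difference of 0.33, and 12 of 38 passed when adjusted over the list alone (camera adjusted p = 8.1e-15, with adjusted p = 0.803 with an estimated correlation). Cholesterol genes had a median difference of 0.39 (camera adjusted p = 9.4e-06, with adjusted p = 0.930 with an estimated correlation). Interferon-stimulated genes had a median difference of -0.80 (camera adjusted p = 1.3e-06, with adjusted p = 0.930 with an estimated correlation), and MHC class I genes -0.48 (camera adjusted p = 0.00139, with adjusted p = 0.930 with an estimated correlation). The interferon-stimulated median was -0.10 without Δ/DN culture 3 and 0.41 without cultures 3 and 4. The MHC class I median was -0.14 without culture 3 and 0.02 without both, and neither list was called without culture 3 (adjusted p = 0.187 for each). Without both cultures camera at the preset correlation called interferon-stimulated genes up (adjusted p = 7.3e-09). Cytokine genes, not called in the full fit, were called up by camera without culture 3 (adjusted p = 3.2e-06). By fry 0 of the 26 lists passed for the difference. With culture as a block the camera test placed 7 lists past the threshold instead of 4, the cell cycle list among them (upward, adjusted p = 0.0437).

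**Figure D4:**
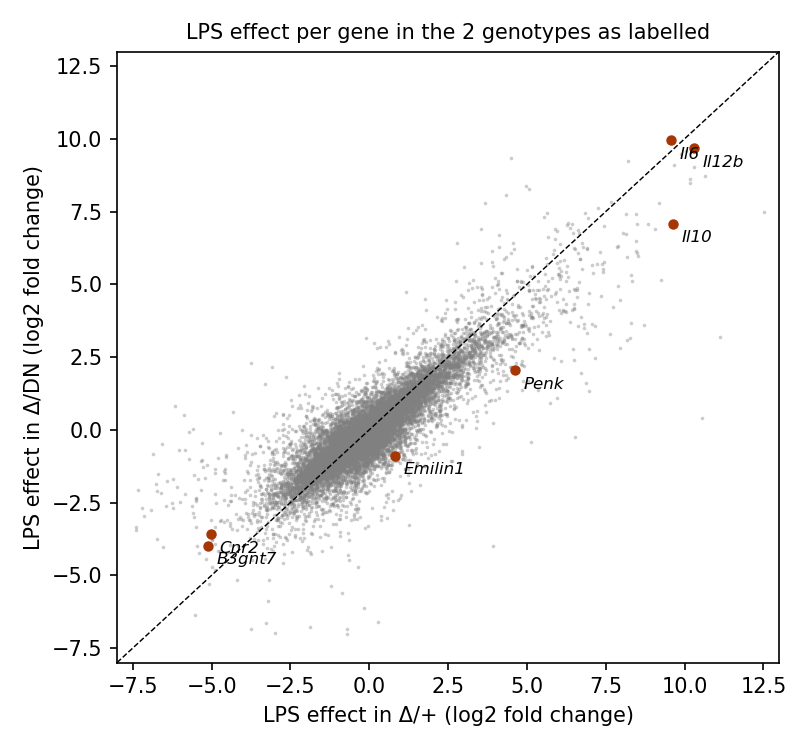
LPS effect (log2 fold change) per gene in Δ/+ on x and Δ/DN on y, 1 point per gene, with a dashed line where both are equal. Of 8227 genes called in both, 8220 changed in the same direction.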

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

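The tests of progenitor markers and of female cells were chosen after their results were seen, as were the spread conditions of the strain, Ddx3x and cell cycle tests, which moved the strain and Ddx3x explanations from excluded to open and no other verdict. Of 657 values tested within groups of 4 libraries, 53 stood apart from the other 3, where chance gives about 1 in 20. Δ/DN US replicate 3 gave 17 of them, Δ/+ US replicate 3 gave 8, and Δ/+ US replicate 4 and Δ/DN LPS replicate 4 gave 7 each.

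In Δ/DN US replicate 3 the following values stood far from those of the other 3 libraries. Gbp5 lay at 173 CPM against 48.1 to 55.5, Nos2 at 10.1 against 0.855 to 1.21, Psme2 at 126 against 65.4 to 69.7 and Tap2 at 142 against 66.7 to 71.7. Cd14 lay at 161 CPM against 55.0 to 61.5, Il1rn at 476 against 227 to 256, Clec4e at 326 against 66.0 to 107, Clec7a at 1006 against 452 to 541 and Car4 at 140 against 17.4 to 29.4. H2-DMa lay at 242 CPM, Ero1a at 111, Sema3c at 1.02 and Marco at 0.898, each above the other 3, and Meis1 at 1.55 and Cd247 at 0.403, each below them. Gzmb lay at 0.013 CPM against 0, which is under the level that 0 reads allow in the other 3 and so no measured difference. The TMM factor of this library, 1.04, compared with 1.30 to 1.33.

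Other libraries stood apart in single values, given in CPM. In Δ/+ US replicate 3 they were Tcf19 (2.36), Trp53 (60.7), Nos2 (1.56), Neurl1b (6.00), Lpar5 (6.39), Cd200r3 (8.18), Cdkn2a (0.694) and Dcn (0.0555, under the level that 0 reads allow in replicate 1). In replicate 4 they were the position on the axis of largest variance (-92.4 against -73.1 to -69.1), Penk (2.44), Cd68 (267), Cd247 (0.338), Ly6c2 (26.8 against 126 to 131), Gzmb (0.163) and Nop56 (81.3), and in replicate 1 Rrp12 (34.3) and Blk (1.70). In Δ/DN US replicate 1 they were Xcr1 (0.388) and Hbb-bt (0.267), in replicate 2 H1f10 (6.58), and in replicate 4 Shisa3 (0.0576), Lcn2 (76.2 against 5.10 to 16.8), Mertk (88.7) and the Y-linked Kdm5d and Eif2s3y at 0. With LPS, Δ/DN replicate 4 stood apart in Tcf19 (2.07), Vegfa (31.0), Nfkb2 (526), Pdcd1lg2 (74.8), Plac8 (12.3), and Kdm5d and Eif2s3y at 0. Δ/DN LPS replicate 2 stood apart in St14 (18.8), Ciita (310) and Dhcr7 (4.05), and replicate 3 in Car4 (258).

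The LPS effects of the genotypes differed by test in Emilin1 (-1.72 log2 units), and by camera in the medians of interferon-stimulated genes (-0.80), MHC class I genes (-0.48), ribosome biogenesis genes (0.33) and cholesterol genes (0.39). With an estimated correlation these lists were not called, at adjusted p = 0.930, 0.930, 0.803 and 0.930, and the interferon-stimulated median was 0.41 and the MHC class I median 0.02 without Δ/DN cultures 3 and 4. Xist, not used in the comparisons, was above the level that 0 reads allow in Δ/+ US replicate 4 (0.0466 CPM), Δ/+ LPS replicates 1 (0.0545) and 2 (0.0645), and Δ/DN replicate 4 without (1144) and with LPS (1166).

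In Δ/DN-labelled US libraries 27 of 40 cell cycle genes rose, with adjusted p = 0.303 for the list with an estimated correlation. Without Δ/DN culture 4 their median was 0.91 (lower limit 0.88 by bootstrap over the list's genes) and without culture 3 it was 1.14 (lower limit 1.05). The median thus did not rest on either culture alone. The bootstrap limits give the spread over genes that move together, not the spread between cultures. More haematopoietic progenitors left in the culture may have contributed. The progenitor markers had a median of 0.22, with a range of -0.30 to 3.30 by bootstrap over these genes. With 5 of 8 higher, this explanation stays open. Neutrophil (1.05), mast cell and basophil (1.31) and erythroid (1.78) markers had medians about as large or larger, with adjusted p = 0.652, 0.637 and 0.303 with an estimated correlation, so other cell types were not excluded either. A direct effect of MYSM1 genotype, as labelled, was not tested.

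Genes with a genotype difference under both treatments could lie near Mysm1 if DNA from another mouse strain had come along with an allele. Of the 100 tested genes nearest to Mysm1, 4% (Cntln, Cdkn2a, Ak4 and Lepr) were called the same way under both treatments, against 3.30% of all genes, a ratio of 1.21 (Fisher's exact p = 0.580). The exact 95% interval of 1.10% to 9.93% just reaches 3 times the share of all genes, so the explanation stays open. Among the 50 nearest genes the share was 2%, with an upper limit of 10.65%. Among the 200 nearest it was 4%, with an upper limit of 7.73% that lies below 3 times the share of all genes. The differences are also what a lasting effect of genotype would give, which was not tested.

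Ddx3y was far lower in Δ/DN culture 3 than in the other cultures with Y-linked reads. RNA of female cells mixed in would have lowered the other Y-linked genes alike, but their lowest ratio to the male mean was 0.825. Reads of Ddx3y given to its X-linked paralog Ddx3x may have played a part: the highest Ddx3x ratio was 0.974, and Ddx3x lay at 293 and 323 CPM where 372 and 416 were needed. With LPS Ddx3x lay below the needed level less 2 SD (343 CPM), which argues against it, but without LPS it lay above that limit (267 CPM), so it stays open. No biological explanation was tested.

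Other groupings of the same libraries were tried 35 ways for each comparison. For genotype without LPS the real split called 2184 genes and the highest other 233, so 1 of 35 reached the real count. With the LPS libraries moved along with their cultures, that other split called 602. A share of 1 of 35 is the smallest that 35 splits can give, so such counts argue against chance but do not exclude it. With LPS the real split called 1795 and the highest other 1218, with Δ/DN LPS replicate 3 on the Δ/+ side, again 1 of 35. A fit of only the LPS libraries called 12 genes, but its set term rested on Δ/DN libraries alone, so that count cannot decide about chance. As 1 of 35 is the smallest share, chance is not excluded with LPS either. For LPS in Δ/+ the counts were 9951 and 6073, and for LPS in Δ/DN 10052 and 26, with 1 of 35 each over all splits. The split with 6073 set Δ/+ US replicates 1, 2 and 3 against the LPS libraries, with only Δ/+ US replicate 4 moved across. It thus kept most of the LPS contrast and is no measure of chance calls. The median of the other Δ/+ splits was 0. US and LPS libraries of a culture pair, and among the 8 splits that part as many pairs the highest other count was 6073 in Δ/+ and 0 in Δ/DN, but 8 splits are too few for a share under 0.05. For the difference between LPS effects the real split called 1 gene and the others 0 (1 of 35), but a count of 1 carries little: limma-voom called 0, and Emilin1 kept its call in 5 of 15 refits. With culture as a block 156 genes compared with 304 when Δ/DN culture 3 was grouped with the Δ/+ cultures, so 2 of 35 splits gave as many, and chance is not excluded. What set that split apart was not tested.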

How the results depend on the processing

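The fits that left out Δ/DN culture 3, culture 4 or both, the sex term and the omission of 7SL RNA were chosen after seeing the data; the other alternatives were planned. No named gene changed direction while called. Over the alternatives, calls of named genes held in 1416 cases and were lost in 278 for genotype without LPS, 1099 and 317 with LPS, 2429 and 31 for LPS in Δ/+, 2475 and 37 for LPS in Δ/DN, and 19 and 12 for the difference between LPS effects. Keeping only calls of at least 1 log2 unit leaves fewer genes by construction, and smaller sets of libraries test with fewer samples; for the other shifts the cause was not tested. Depth limits genes near the floor, such as Xcr1, Shisa3 and Lum.

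Leaving out 1 library gave 174 to 3403 calls for genotype without LPS, 90 to 2233 with LPS, 8742 to 9556 for LPS in Δ/+, 8955 to 10170 for LPS in Δ/DN and 0 to 15 for the difference. The log2 difference of Mysm1 then ranged from -0.39 to -0.17, -0.33 to -0.24, -0.27 to -0.18, -0.37 to -0.10 and -0.18 to 0.15 in the same order.

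Genotype without LPS, 2184 calls, gave 1270 without the library set term, 1271 in library set 2, 3460 by DESeq2, 3994 with replicate number as a block, 3705 without Δ/DN culture 3, 1417 without cultures 3 and 4, and 657 of at least 1 log2 unit. The balance moved too: 1046 up and 1138 down became 410 and 861 in set 2, 98 and 252 without Δ/DN US replicate 2, and 502 and 155 among changes of at least 1 log2 unit. With LPS, 1795 calls became 3017 by DESeq2, 12 with only the groups compared, 3809 with replicate number as a block, 2878 without culture 3 and 659 of at least 1 log2 unit. LPS gave 5466 calls in Δ/+ and 4899 in Δ/DN of at least 1 log2 unit. The difference between LPS effects, 1 call, gave 4 in set 2, 34 with no low-count filter, 118 by DESeq2, 0 by limma-voom, 156 with culture as a block, 44 without culture 3, 2 without culture 4, 9 without both and 2 with the sex term. The 688 genes shared between genotype comparisons became 401 without the library set term and 1317 without culture 3.

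With an estimated correlation 0 lists passed camera for genotype without LPS, 0 with LPS, 0 for LPS in Δ/+, 2 for LPS in Δ/DN and 0 for the difference. The 4 lists of the difference became 8 in set 2, 7 with culture as a block and 8 without cultures 3 and 4. Without LPS, interferon-stimulated genes, not called in the full fit, were called lower in Δ/DN in set 2 (adjusted p = 7.4e-31) and without both cultures (5.7e-32). Maturation genes (0.740 and 0.748) and MHC class I genes (0.752 and 0.764) lost their upward call there and were not shown to be lower. In the difference, cytokine genes, not called in the full fit, were called up in set 2 (1.6e-08), without culture 3 (3.2e-06) and without both (1.3e-08), interferon-stimulated genes, called down in the full fit, were called up in set 2 (1.3e-08) and without both (7.3e-09), and the cell cycle list was called up with culture as a block alone (0.0437). The culture block moved no other count of calls by more than 1.5 times. Mysm1 became called without LPS with the sex term (-0.37), with LPS without culture 3 (-0.29) or both (-0.31), and for LPS in Δ/DN in set 2 (-0.29), without Δ/DN US replicate 3 (-0.37), without culture 3 (-0.29) or both (-0.31).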

Other observations

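The genes and the gene family below were chosen after seeing the data. Replication-dependent histone genes, the only histone genes taken here, were higher in Δ/DN as labelled. Without LPS 54 of 65 tested rose and 65 lay higher, with a median log2 difference of 1.14, and with LPS 32 rose with a median of 1.24. Their rise was not tested apart from that of the cell cycle list, whose median was 1.07 without LPS. With LPS 20 fell in Δ/+ and 24 in Δ/DN (medians -0.75 and -0.72), and the edgeR test of the difference between LPS effects called 0. Of the 65, 28 were called the same way between genotypes under both treatments. The count of 54 was 63 without Δ/DN culture 3, 58 without culture 4 and 16 without both. It was 0 without Δ/+ US replicate 4 (the only Δ/+ library of set 3), 6 without replicate 2 and 18 without replicate 1, and 3 without Δ/DN US replicate 2 and 14 without replicate 4. In these 5 refits the median stayed between 0.98 and 1.13, with 65 of 65 higher each time. Many histone genes are near-identical copies, so the placement of reads on single copies is uncertain.

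Cdkn2a, which encodes the cell cycle inhibitor p16 and the p53 activator ARF, rose in Δ/DN by 2.17 ± 0.32 log2 units without LPS (0.406 to 1.66 CPM) and 2.32 ± 0.36 with LPS (0.501 to 2.17 CPM). The lipase genes Lipo3 (-1.41 ± 0.10 without and -1.30 ± 0.11 with LPS) and Lipo2 (-1.45 ± 0.17 and -1.34 ± 0.19) fell under both treatments, Lipo3 from 15.9 to 6.10 CPM without LPS. Lepr, the leptin receptor gene, fell by 1.08 without and by 1.84 with LPS. Cdkn2a and Lepr are among the 100 tested genes nearest to Mysm1, where DNA from another strain was not excluded. Fmr1nb lay at 5.42 and 8.88 CPM without and 10.7 and 11.8 CPM with LPS in Δ/DN cultures 1 and 2, and at 0.0967 CPM or less in the other 11 libraries.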
